A study of Mus musculus with 6 samples.

How the data were processed

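RNA sequencing of lung tissue from wild-type mice was deposited for 6 samples in 2 groups, PM and its PBS vehicle, with replicate numbers 1 to 3 in each. Per the labels' protocols, total RNA was isolated with the easy-BLUE kit and libraries were made with Lexogen's SENSE mRNA-Seq kit, which selects polyadenylated RNA. Per the submitters' processing notes, TopHat, a spliced aligner, Cufflinks, a transcript assembler, and the mouse build mm10 are named. Their versions and roles, the program that counted reads, the annotation and whether counting used strand are not given in the sources used here. The values deposited by the authors are raw counts of reads per gene symbol, whole numbers with a different total in each distinct library and no normalization. Without known strand use, reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart. Of 144 names examined, 26 share exon sequence with another gene in the GENCODE M21 annotation, 7 of them with a tested gene: Atf5, Egfl7, Mmp19, Plet1, Rpl32, Rps2 and Txndc5. Counts of close paralogs (Orm, Chil, Mt, Mx, haemoglobin and ribosomal protein genes) are uncertain where reads could be divided among copies.

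The table of PBS replicate 2 is identical to that of PBS replicate 1 in all 23282 entries, and its header names the other library. The design fixed before the data were examined assumed 6 libraries. The pair was therefore counted as 1 library, leaving 2 PBS and 3 PM libraries, and the fit on all 6 as deposited was added as an alternative after the data were seen. The labels do not say that samples came from separate animals, so p-values measure only the spread between these samples. A blank entry with no gene name in the PBS replicate 1 table was left out. Of 23238 symbols, 79 entries shared a symbol with another; the entry with the highest total was kept for each, which set aside 44 entries with 0.0246% of counts. Of the symbols, 22024 matched RefSeq names for GRCm38, the same assembly as mm10, from which coordinates were taken.

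Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled by TMM (trimmed mean of M values), and PM was compared with PBS by edgeR's quasi-likelihood test with robust estimation, two-sided, with no covariates. Genes were called at a Benjamini-Hochberg adjusted p below 0.05 over 14057 tested genes. Fold changes are PM minus PBS on the log2 scale, with the standard error taken as the fold divided by the square root of the F statistic, and levels are TMM-scaled CPM (counts divided by the scaled library total and brought to a common total), computed from the deposited counts. For genes at 0 counts in both PBS libraries the fold was bounded against a floor of 3 counts per library.

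Before the data were examined, 54 gene lists were written for the lung, for particle exposure and for tissues a lung piece can carry along; 60 of their 747 genes are in more than 1 list. The 50 lists with at least 5 tested members were compared with other genes by camera of limma 3.58.1 with a preset correlation of 0.01, and beside it with a correlation estimated from the data and by fry. Lists of basal and squamous epithelium (1 tested member), neuroendocrine cells (4), thyroid, oesophagus and thymus (3) and sex-linked genes (1) had too few tested members. The rule for naming genes, fixed at the same time, took the 10 largest rises and falls among called genes with no overlap between groups and a mean of at least 1 CPM, leaving out unnamed gene models and pseudogenes. It added the 3 members with the smallest p, in the direction of the list, of every list past camera, and 14 exposure markers whatever their result. Genes chosen after their values were seen are named as such. Some genes that this rule chose are not reported here.

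The procedure was tested on simulated counts for the comparison of PM with PBS. They were drawn for the 14057 tested genes at the real means and library sizes, and 13868 genes passed the filter. The changed genes were picked only above a minimum mean count, so the recovery does not cover genes with few counts. The procedure recovered 59% of 100 genes changed by 2-fold and 93% of 100 changed by 4-fold, with 0 wrong signs. Of its 173 calls 21 were false, a larger share than the level of 0.05 aims at. In the real data 133 genes were at least 4-fold higher with all PM libraries above all PBS libraries, and 4 were called. The simulated recovery therefore cannot be taken as that of the real data. Alternatives were another scaling, other filters on low counts, each library left out in turn, the replicate number as a block, DESeq2 1.42.0, limma-voom, an adjusted p of 0.10, a minimum of 1.5-fold, non-robust estimation, and, added after the data were seen, all 6 tables and the counts without Rn45s and haemoglobin genes. With total counts from 7410200 to 8827202, the depth behind each gene is its count, floors cover counting error only, and bootstrap intervals cover the spread between list members.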

Results

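Gene expression was measured by RNA sequencing in lung tissue of wild-type mice that had received PM or its vehicle, phosphate-buffered saline (PBS), by the route the labels abbreviate i.t. The series title describes the exposure as chronic, and the question addressed was how it changes gene expression in the lung. The labels give neither the dose nor the duration and do not spell out PM. There were 3 samples in each group, each with a table of read counts for the same 23282 gene entries. The tables of PBS replicates 1 and 2 were identical in all 23282 entries, whereas PBS replicates 1 and 3 were equal in 229 of the 13796 entries with at least 10 counts. The identical pair differed by less than sampling noise and was counted as 1 sample, so that 2 distinct PBS libraries were compared with 3 PM libraries. Total counts were 8827202 and 7660937 in PBS replicates 1 and 3, and 8798953, 7558460 and 7410200 in PM replicates 1, 2 and 3. At these depths a count of 0 allows up to 0.348 to 0.430 CPM (counts scaled to a common library total), a floor that covers counting error only.

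The PBS libraries resembled each other more than the PM libraries did. Across genes, which are not independent replicates, the correlation of log2 CPM was 0.976 between the PBS libraries, 0.952 to 0.967 among the PM libraries and 0.934 to 0.963 between groups. The leading principal component took up 47.9% of the variance, with scores of -31.0 and -36.4 for PBS and 15.9, 50.0 and 1.54 for PM replicates 1, 2 and 3. Rn45s, the ribosomal RNA precursor, took 18.2% and 16.3% of counts in PBS and 23.6%, 25.4% and 15.7% in PM. Haemoglobin genes took 5.41% in PBS replicate 1, 1.60% in PBS replicate 3, and 1.82%, 1.52% and 0.632% in PM. Y-linked genes were at 0 counts apart from 1 count of Eif2s3y in PM replicate 2, and Xist was counted in every library.

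**Figure D1:**
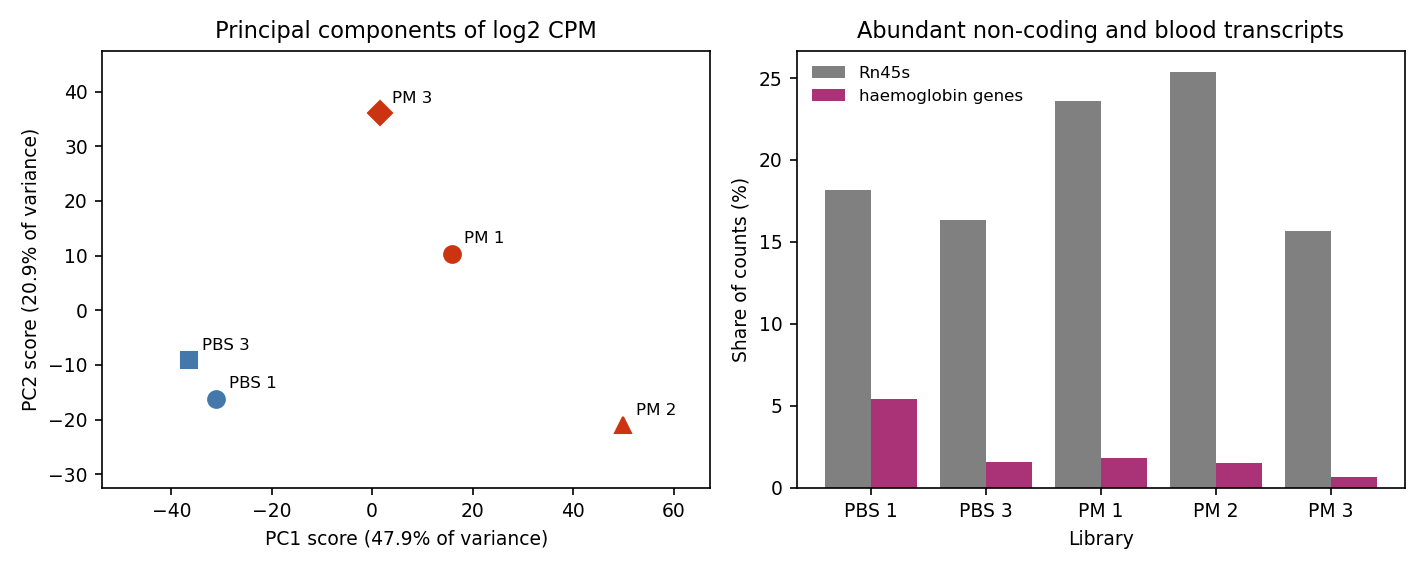
Left, scores of the 5 distinct libraries on the leading principal components of log2 CPM (PC1, 47.9% of variance; PC2, 20.9%), with PBS in blue and PM in red. Right, the percentage of each library's counts taken by Rn45s (grey) and by haemoglobin genes (purple). PM replicate 2 lies farthest from the PBS libraries on PC1, and PBS replicate 1 has the highest haemoglobin share, 5.41%.

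The genes higher in PM lung included 2 metallothioneins, the acidic chitinase and the joining chain of antibodies, and those lower a Wnt ligand and a non-muscle myosin. Of 14057 genes tested, 32 changed: 20 rose and 12 fell (edgeR's quasi-likelihood test, two-sided, Benjamini-Hochberg adjusted p below 0.05, n = 2 PBS and 3 PM libraries). Jchain, the joining chain of secreted IgA and IgM, had the largest rise, from 4.51 ± 1.49 to 63.7 ± 15.6 CPM (mean ± SD). Its log2 fold was 3.81 ± 0.29 SE, with an adjusted p of 0.00305 by edgeR with Benjamini-Hochberg adjustment, and it lies on chromosome 5 at 88519809 to 88527897 in GRCm38. Glb1l2, a beta-galactosidase-like gene, had the largest fall, from 61.2 ± 0.549 to 26.5 ± 4.14 CPM. It lies on chromosome 9 at 26763044 to 26806473, and its log2 fold was -1.21 ± 0.16 SE, with an adjusted p of 0.0147 by the same edgeR test with Benjamini-Hochberg adjustment.

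The next largest rises, as log2 folds, were those of Orm2, an acute phase protein (3.29 ± 0.56 SE), Fcgr2b, the inhibitory IgG receptor (2.88 ± 0.40), Wfdc17, a secreted whey acidic protein family member (2.80 ± 0.35), and Prom1, an apical membrane protein of epithelia (1.92 ± 0.29). Ctsk, a lysosomal protease, rose by 1.88 ± 0.23, Mt2, a metallothionein, by 1.84 ± 0.20, Clec4a2, a myeloid lectin, by 1.77 ± 0.27, Chia1, the acidic chitinase, by 1.67 ± 0.17, and Ccl17, a ligand of CCR4, by 1.65 ± 0.27. Among the falls, Wnt2, a Wnt ligand of the lung mesenchyme, had a log2 fold of -1.06 ± 0.17 SE, Tmem119 of -1.02 ± 0.13, Scn3a, a sodium channel, of -1.01 ± 0.17 and Scube2 of -0.92 ± 0.15. Hilpda, a lipid droplet protein induced by hypoxia, fell by 0.85 on the log2 scale, Myh10, a non-muscle myosin, by 0.80, Sept4 by 0.78, and Ablim3 and Zbtb20 by 0.76 each. Others of the 32, named after their values were seen where no rule had chosen them, were Mt1, Ccr2, Csf2rb, Cd44, Lgals3, Gpx2, Sox2, F7 and S100a4, all higher, with log2 folds from 0.74 to 1.62. Limch1 and Atf5 were lower, with log2 folds of -0.71 and -0.70. Exons of Atf5 overlap those of Nup62 on the opposite strand. The size of the Orm2 fold is uncertain, since both PBS libraries together held 12 counts of it.

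The number of called genes depended on single libraries: 1 gene without PBS replicate 1 (Jchain, log2 fold 4.20), 6 without PBS replicate 3, and 12, 106 and 427 without PM replicates 1, 2 and 3. DESeq2 called 369 genes, with all 32 among them, and 206 genes passed an adjusted p of 0.10 by edgeR with Benjamini-Hochberg adjustment. At an unadjusted p below 0.05 there were 1871 genes, 1021 higher and 850 lower. All PM libraries lay above all PBS libraries for 15.5% of genes and below them for 16.1%, where chance gives 10% each way.

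**Figure D2:**
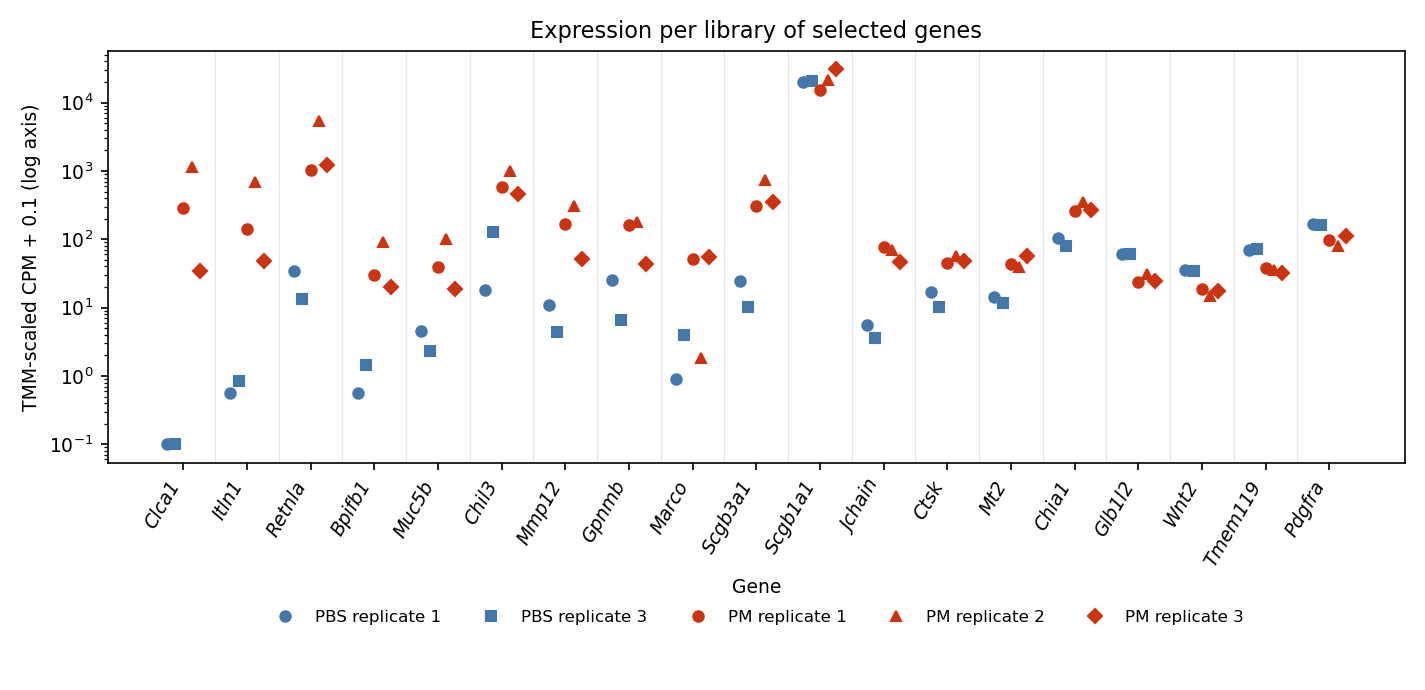
Expression of 19 genes in each of the 5 distinct libraries, as TMM-scaled CPM plus 0.1 on a log axis, with PBS in blue and PM in red. Clca1 was at 0 counts in both PBS libraries and between 33.9 and 1161 CPM in PM. Jchain, Ctsk, Mt2, Chia1, Glb1l2, Wnt2 and Tmem119 passed the test, with no overlap between groups, and Marco was at 1.72 CPM in PM replicate 2 and above 52 CPM in the other PM libraries.

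Genes of type 2 immunity and of mucus-secreting airway cells had the largest median folds of the gene lists fixed beforehand. In the list of type 2 and allergic response genes the median log2 fold was 4.49, and all PM libraries lay above all PBS libraries for 13 of 15 tested members. In the mucous cell list the median was 4.45 over 9 members, 8 of them with no overlap between groups. Clca1, a secreted goblet cell protein, was at 0 counts in both PBS libraries and at 288, 1161 and 33.9 CPM in PM replicates 1, 2 and 3. Retnla (RELM-alpha, a marker of alternatively activated macrophages) stood at 23.8 ± 14.6 CPM in PBS and 2520 ± 2429 CPM in PM, and Itln1 (intelectin-1, a lectin of goblet cells) at 0.602 ± 0.196 and 296 ± 353 CPM. Tff2, a trefoil peptide, stood at 0.301 ± 0.0981 and 40.5 ± 44.8 CPM. Ccl8 had a log2 fold of 4.99. Chil3, a macrophage chitinase-like protein of neither list, stood at 18.2 and 127 CPM in PBS and had a log2 fold of 3.24 (adjusted p = 0.400 by edgeR with Benjamini-Hochberg adjustment). These 6 genes were chosen after their values were seen, and reads of Chil3 may be shared with its close paralogs. Of members chosen by rule, Ccl17 rose. Alox15 (log2 fold 5.04, adjusted p = 0.0525) and Il1rl1, the IL-33 receptor (1.88, 0.0592), did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the same edgeR test with Benjamini-Hochberg adjustment, Bpifb1 (5.69, 0.250), Agr2 (3.38, 0.240), Foxa3 (2.05, 0.220) and Muc5b (3.98, 0.319) did not pass either. Alox15 had 2 counts in all in PBS, at 0.232 and 0 CPM, so the size of its fold is uncertain.

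In edgeR's test over all genes, 1 of the 15 type 2 members and 0 of the 9 mucous members rose. Adjusted over the list alone, 8 and 0 rose. At an unadjusted p below 0.05, 10 and 6 were higher, and DESeq2 called 11 and 7, limma-voom 0 and 0. Camera of limma tests whether a list stands apart from other genes. With the preset correlation and Benjamini-Hochberg adjustment, both lists stood higher by camera (adjusted p = 6.47e-26 and 5.32e-19). With an estimated correlation neither passed camera (adjusted p = 0.164 for each). The estimated correlations between members were 0.604 and 0.862, far above the preset 0.01, so the smaller p-values overstate the evidence. PM replicate 2 had the highest values, with list medians of 3.61 for type 2 and 5.28 for mucous genes on a log2(CPM + 0.5) scale relative to PBS, against 1.92 and 3.58 in PM replicate 1 and 1.84 and 2.38 in PM replicate 3. Without PM replicate 2 the type 2 median was 2.73 and the mucous median 3.95.

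Macrophage, lysosomal and matrix-degrading genes were higher as groups. The alveolar macrophage list had a median log2 fold of 1.21 (16 tested, 1 rose; adjusted over the list alone, 9 rose). Ctsk rose within it, with Plet1 at 0.89 and Lpl, lipoprotein lipase, at 0.56 not past the test. The lysosome and phagocytosis list had a median of 0.69 over 22, 1 of which rose, again Ctsk. Adjusted over the list alone, 11 rose and 1 fell, the scavenger receptor Cd36 at a log2 fold of -0.30 (named after its values were seen). Cd36 was not called over all genes (adjusted p = 0.290 by edgeR with Benjamini-Hochberg adjustment). It is also in the lipid handling list, where 0 fell adjusted over the list alone. The lysosomal proteins Ctsd and Npc2 were at 0.74 and 0.69. Matrix-degrading enzymes had a median of 0.90 over 12, of which 1 rose, also Ctsk, and 4 rose adjusted over the list alone. The metalloproteinase Mmp8 was at 1.74, and Mmp19 at 19.8 ± 0.466 CPM in PBS and 39.7 ± 6.81 CPM in PM. All these lists stood higher by camera of limma with Benjamini-Hochberg adjustment (adjusted p = 7.24e-20, 1.15e-14 and 9.60e-09), each with adjusted p = 0.164 with an estimated correlation. In the list of interstitial and monocyte-derived macrophages (median 1.17 over 18), Tmem119, best known as a marker of microglia, fell. Adjusted over the list alone, 5 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 6.23e-06; adjusted p = 0.267 with an estimated correlation). Lipid handling genes had a median of 0.31 over 17 (0 rose, 7 higher and 1 lower at an unadjusted p below 0.05, 3 called by DESeq2; adjusted over the list alone, 2 rose), with Fabp5 at 0.49 and Trem2 at 1.89 ± 0.930 CPM in PBS and 7.73 ± 5.42 CPM in PM. Camera with Benjamini-Hochberg adjustment placed that list higher (adjusted p = 0.000383; adjusted p = 0.164 with an estimated correlation). The alveolar macrophage median was 0.68 without PBS replicate 1, the interstitial macrophage median 0.74 without PM replicate 2 and the lipid handling median 0.19 without PBS replicate 3.

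Monocyte, neutrophil and acute phase genes were also higher. In the monocyte list (median 0.38 over 14; adjusted over the list alone, 4 rose), Ccr2, the receptor for CCL2, rose from 25.9 ± 0.232 to 63.0 ± 9.90 CPM, with Vcan at a log2 fold of 1.89 and Ly6c2 at 0.78. Neutrophil genes had a median of 1.15 over 13, with the granule proteins Ltf at 3.99, Lcn2 at 2.26 and Mmp8 at 1.74. The list medians relative to PBS were 0.528, 0.467 and 1.89 in PM replicates 1, 2 and 3. Mmp8 was also highest in PM replicate 3. Ltf (9.58, 25.5 and 8.58 CPM) and Lcn2 (207, 354 and 193 CPM) were instead highest in PM replicate 2. Lcn2 is also a member of the acute phase list. None of the 13 rose in edgeR's test, 4 rose adjusted over the list alone, 4 were higher at an unadjusted p below 0.05 and DESeq2 called 4. The acute phase list had a median of 2.40 over 10, and 5 rose adjusted over the list alone. Within it Orm2 rose, and Fgg, a fibrinogen chain, had a log2 fold of 3.74. Fgg had 3 counts in all in PBS, so the size of its fold is uncertain. By camera of limma with Benjamini-Hochberg adjustment the monocyte, neutrophil and acute phase lists stood higher (adjusted p = 4.86e-05, 9.60e-09 and 2.23e-13; adjusted p = 0.164, 0.198 and 0.164 with an estimated correlation). Medians were 0.21 for monocytes and 0.31 for neutrophils without PM replicate 3, 1.92 for neutrophils without PBS replicate 1 and 1.02 for acute phase genes without PM replicate 2.

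Inflammatory cytokines and chemokines had a median log2 fold of 1.39 over 19 members, none of which passed edgeR's test over all genes. Cxcl1 and Cxcl3, which attract neutrophils, were at 2.40 ± 0.60 SE and 2.68 ± 0.80, and Il33 at 1.02 ± 0.28. Adjusted over the list alone, 4 rose, 8 were higher and 1 lower at an unadjusted p below 0.05, and DESeq2 called 4. Proliferation genes had a median of 1.54 over 20, with the mitotic genes Ccnb1 at 3.32 and Ccnb2 at 2.01 and Tpx2 at 1.07 ± 0.290 CPM in PBS and 8.74 ± 6.34 CPM in PM. Of these, 0 rose over all genes and 3 adjusted over the list alone, with 14 higher at an unadjusted p below 0.05 and 5 called by DESeq2. Both lists stood higher by camera with Benjamini-Hochberg adjustment (adjusted p = 1.17e-06 and 1.48e-10; adjusted p = 0.310 and 0.333 with an estimated correlation). Their medians were 0.83 and 0.80 without PM replicate 2.

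Interferon-stimulated genes (median 1.16 over 20) and genes of MHC class II and antigen presentation (0.83 over 12) were led by PM replicate 2. The interferon list medians relative to PBS were 0.43, 2.11 and -0.08 in PM replicates 1, 2 and 3, and the MHC class II medians 0.73, 1.36 and -0.02. Mx2, an interferon-induced GTPase, had a log2 fold of 3.57, Mx1 of 3.53 and Ifit3 of 0.50, and Ctss, H2-Aa and H2-Eb1 stood at 1.53, 0.89 and 0.72. In edgeR's test 0 members of either list rose, with 1 interferon gene and 0 MHC class II genes higher at an unadjusted p below 0.05, the same numbers called by DESeq2, and 1 and 0 adjusted over the list alone. Camera with Benjamini-Hochberg adjustment placed both higher (adjusted p = 0.000104 and 0.000147; adjusted p = 0.531 and 0.400 with an estimated correlation). Without PM replicate 2 the interferon median was 0.14 (camera, Benjamini-Hochberg adjusted p = 0.490) and the MHC class II median 0.39.

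Among lymphocytes, the plasma cell list (median 0.20 over 9) had 1 member that rose, Jchain, also when adjusted over the list alone. The other plasma cell genes ranked next, Derl3 and Txndc5, which act in the endoplasmic reticulum, were at 1.66 and 0.27 (camera, Benjamini-Hochberg adjusted p = 2.84e-05; adjusted p = 0.164 with an estimated correlation). The median was 0.40 without PBS replicate 1 and 0.31 without PM replicate 3. NK and cytotoxic genes were lower, with a median of -0.60 over 11: Gzma, a granzyme, was at -1.08 ± 0.27 SE, Ncr1 at -1.02 and Ccl5 at -0.86. Of these 0 fell over all genes, 1 fell adjusted over the list alone, 2 were lower at an unadjusted p below 0.05 and DESeq2 called 1 (camera, Benjamini-Hochberg adjusted p = 0.000187; adjusted p = 0.329 with an estimated correlation). T cell genes had a median of 0.36 over 14, with Icos at 1.72, Cd4 at 0.67 and Il7r at 0.45. In that list 0 rose over all genes or adjusted over the list alone, 4 higher at an unadjusted p below 0.05 and 0 called by DESeq2 (camera, Benjamini-Hochberg adjusted p = 0.0334; adjusted p = 0.534 with an estimated correlation). That call was lost without PBS replicate 1, PM replicate 1 or PM replicate 2 (adjusted p = 0.288, 0.165 and 0.199), and the NK median was -1.03 without PM replicate 2 and -0.38 without PM replicate 3. B cell genes had a median of 0.07 and a mean of 0.02 while the test pointed down (camera, Benjamini-Hochberg adjusted p = 0.644), and lymphoid aggregate genes a median of 0.24 (0.390). Without PM replicate 1 the B cell median was -0.31 (0.00152), and the lymphoid aggregate median was 0.33 without PM replicate 3 (0.0466). Dendritic cell genes had a median of 0.66 over 14, with Ccl17 risen, Clec10a at 0.98 and Fscn1 at 0.99. Adjusted over the list alone, 6 rose and 1 fell (camera, Benjamini-Hochberg adjusted p = 0.00180; adjusted p = 0.400 with an estimated correlation). Complement genes had a median of 0.15 over 13, with C1qc at 1.43, C1qb at 0.97 and C3 at 0.80. In that list 0 rose over all genes or adjusted over the list alone, 1 was higher and 1 lower at an unadjusted p below 0.05 and DESeq2 called 1 (camera, Benjamini-Hochberg adjusted p = 0.0334; adjusted p = 0.534 with an estimated correlation). Their call was lost without PBS replicate 3 or PM replicate 2 (0.0845 and 0.192). Eosinophil, basophil and mast cell genes had a median of 0.21 over 6 tested members (0.396).

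Metallothioneins rose, and antioxidant genes were higher as a group. Mt1 rose from 46.1 ± 1.57 to 142 ± 26.3 CPM (log2 fold 1.62 ± 0.16 SE, adjusted p = 0.00400) and Mt2 from 12.9 ± 1.62 to 46.2 ± 8.93 CPM (1.84 ± 0.20, adjusted p = 0.00645, both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). They were the only 2 of 8 metal response genes that rose, also when adjusted over the list alone, and the heat shock gene Hspa1a was at 0.86. The metal response median was 0.49, and 0.01 without PBS replicate 1 and 0.97 without PBS replicate 3. In the list of NRF2 targets and oxidative stress genes (median 0.45 over 20; adjusted over the list alone, 9 rose), Gpx2, a glutathione peroxidase, rose by 1.40 ± 0.22 SE, with the cystine transporter Slc7a11 at 2.61 and glutathione reductase Gsr at 0.81. Targets of the aryl hydrocarbon receptor had a median of 0.61 over 9 (0 rose, 4 higher at an unadjusted p below 0.05, 2 called by DESeq2; adjusted over the list alone, 3 rose), with Cyp2s1 at 0.74, Cyp1b1 at 1.92 ± 0.60 SE and Scin at 0 counts in both PBS libraries and 0.584, 4.87 and 1.26 CPM in PM replicates 1, 2 and 3. Camera with Benjamini-Hochberg adjustment placed the metal, NRF2 and aryl hydrocarbon receptor lists higher (adjusted p = 2.24e-05, 1.64e-09 and 0.00169; adjusted p = 0.310, 0.164 and 0.310 with an estimated correlation). Without PM replicate 3 the aryl hydrocarbon receptor median was 0.16 (0.233).

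Of the 14 exposure markers fixed beforehand, Mt2 alone rose in edgeR's test, and DESeq2 called 4 higher: Mt2, Cxcl1, Mmp12 and Muc5b. Cyp1a1, the classical aryl hydrocarbon receptor target, had 2 to 5 counts per library and was not tested, and Muc5ac, a gel-forming airway mucin, had 0 counts in both PBS libraries and 9, 41 and 0 in PM replicates 1, 2 and 3. Heme oxygenase Hmox1 was at 0.39 ± 0.48 SE and the quinone reductase Nqo1 at -0.30 ± 0.65, both within their errors. Mmp12, the macrophage elastase, stood at 7.61 ± 4.65 CPM in PBS and 175 ± 126 CPM in PM, Gpnmb, a lysosomal glycoprotein, at 16.0 ± 13.5 and 127 ± 73.5, and Saa3, an acute phase protein, at 8.63 ± 6.14 and 54.4 ± 64.2. Marco, the scavenger receptor for particles, was at 0.811 and 3.83 CPM in PBS and at 52.1, 1.72 and 55.4 CPM in PM. Ccl2 was at a log2 fold of 1.36 ± 0.59 SE and Il1b at 1.11 ± 0.81. The adjusted p of Mmp12, Gpnmb, Saa3, Marco, Ccl2, Il1b, Hmox1 and Nqo1 lay between 0.308 and 0.894 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

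Ciliated cell genes and club and secretory cell genes were higher as lists. The ciliated list had a median log2 fold of 0.81 over 15 members, with the axonemal genes Cfap126 at 1.05 ± 0.20 SE, Dnah5 at 1.17 ± 0.24 and Tmem212 at 0.92 ± 0.19. Of these, 0 rose over all genes, 7 rose adjusted over the list alone, 11 were higher at an unadjusted p below 0.05 and DESeq2 called 4. Club and secretory genes had a median of 0.39 over 13 (0 rose, 3 higher at an unadjusted p below 0.05, 3 called by DESeq2; adjusted over the list alone, 2 rose). Within it the secretoglobin Scgb3a1 stood at 17.2 ± 9.80 CPM in PBS and 467 ± 237 CPM in PM, and Reg3g, an antimicrobial lectin, at 2.39 ± 2.68 and 75.1 ± 54.1, with Cyp2a5 at a log2 fold of 1.22. Scgb1a1, the club cell secretory protein, was at 0.15 ± 0.25 SE, Scgb3a2 at 0.39 ± 0.36 and Cyp2f2 at 0.11 ± 0.26 (chosen after their values were seen), and all 3 turned negative without PM replicate 3 (-0.14, -0.0017 and -0.21). Both lists stood higher by camera with Benjamini-Hochberg adjustment (adjusted p = 1.20e-09 and 2.57e-05; adjusted p = 0.317 and 0.310 with an estimated correlation), and the club list was no longer called without PM replicate 3 (median -0.0017, adjusted p = 0.0605).

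Endothelial, fibroblast, alveolar type 1 and mesothelial genes had lower medians, whereas alveolar type 2 genes did not. Endothelial genes had a median of -0.36 over 18 members, with Tie1 at -0.62 ± 0.12 SE, Egfl7 at -0.57 ± 0.12 and Cdh5 (VE-cadherin) at -0.39 ± 0.11. Of these, 11 fell adjusted over the list alone, none over all genes, 11 were lower at an unadjusted p below 0.05 and DESeq2 called 2. Fibroblast genes had a median of -0.32 over 14, with Pdgfra at -0.78 ± 0.14, Inmt at -0.76 ± 0.15 and Col13a1 at -0.79 ± 0.20. Of these, 4 fell adjusted over the list alone, none over all genes (5 at an unadjusted p below 0.05, 3 by DESeq2). Alveolar type 1 genes had a median of -0.32 over 13, with Akap5 at -0.51, Ager at -0.41 and Pdpn at -0.34. In that list 3 fell adjusted over the list alone, none over all genes (5 at an unadjusted p below 0.05, 2 by DESeq2). Mesothelial genes had a median of -0.33 over 9, with Nkain4 at -0.56, Lrrn4 at -0.42 and Gpm6a at -0.21. In that list 0 fell over all genes or adjusted over the list alone (2 at an unadjusted p below 0.05, 0 by DESeq2). These lists stood lower by camera with Benjamini-Hochberg adjustment (adjusted p = 6.52e-06, 3.29e-05, 0.000158 and 0.0104; adjusted p = 0.317, 0.164, 0.164 and 0.400 with an estimated correlation). The mesothelial call was lost without PBS replicate 1 (median -0.15, adjusted p = 0.145). Alveolar type 2 genes had a median of 0.19 over 16, with Chil1 at 2.59, Il33 at 1.02 and the surfactant protein Sftpd at 0.88. In that list 0 rose over all genes or adjusted over the list alone, 5 were higher and 1 lower at an unadjusted p below 0.05, and DESeq2 called 2. Camera with Benjamini-Hochberg adjustment placed it higher (adjusted p = 0.00296; adjusted p = 0.466 with an estimated correlation), but not without PBS replicate 3 (median 0.01, adjusted p = 0.356). In the list of injury-associated alveolar epithelium (median 0.23 over 13; adjusted over the list alone, 2 rose), Lgals3, galectin-3, rose by 0.85 ± 0.13 SE, with Clu at 0.60 and Areg at 0.90 (camera, Benjamini-Hochberg adjusted p = 0.0262; adjusted p = 0.534 with an estimated correlation). That call was lost without PBS replicate 3 (median -0.0039, adjusted p = 0.407) or PM replicate 2 (0.13, 0.344). Smooth muscle and pericyte genes had a median of -0.20 (0.0632) and lymphatic endothelial genes of -0.14 (0.182), and the former passed without PBS replicate 3, PM replicate 1 or PM replicate 2 (0.0208, 0.0185 and 0.0209).

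**Figure D3:**
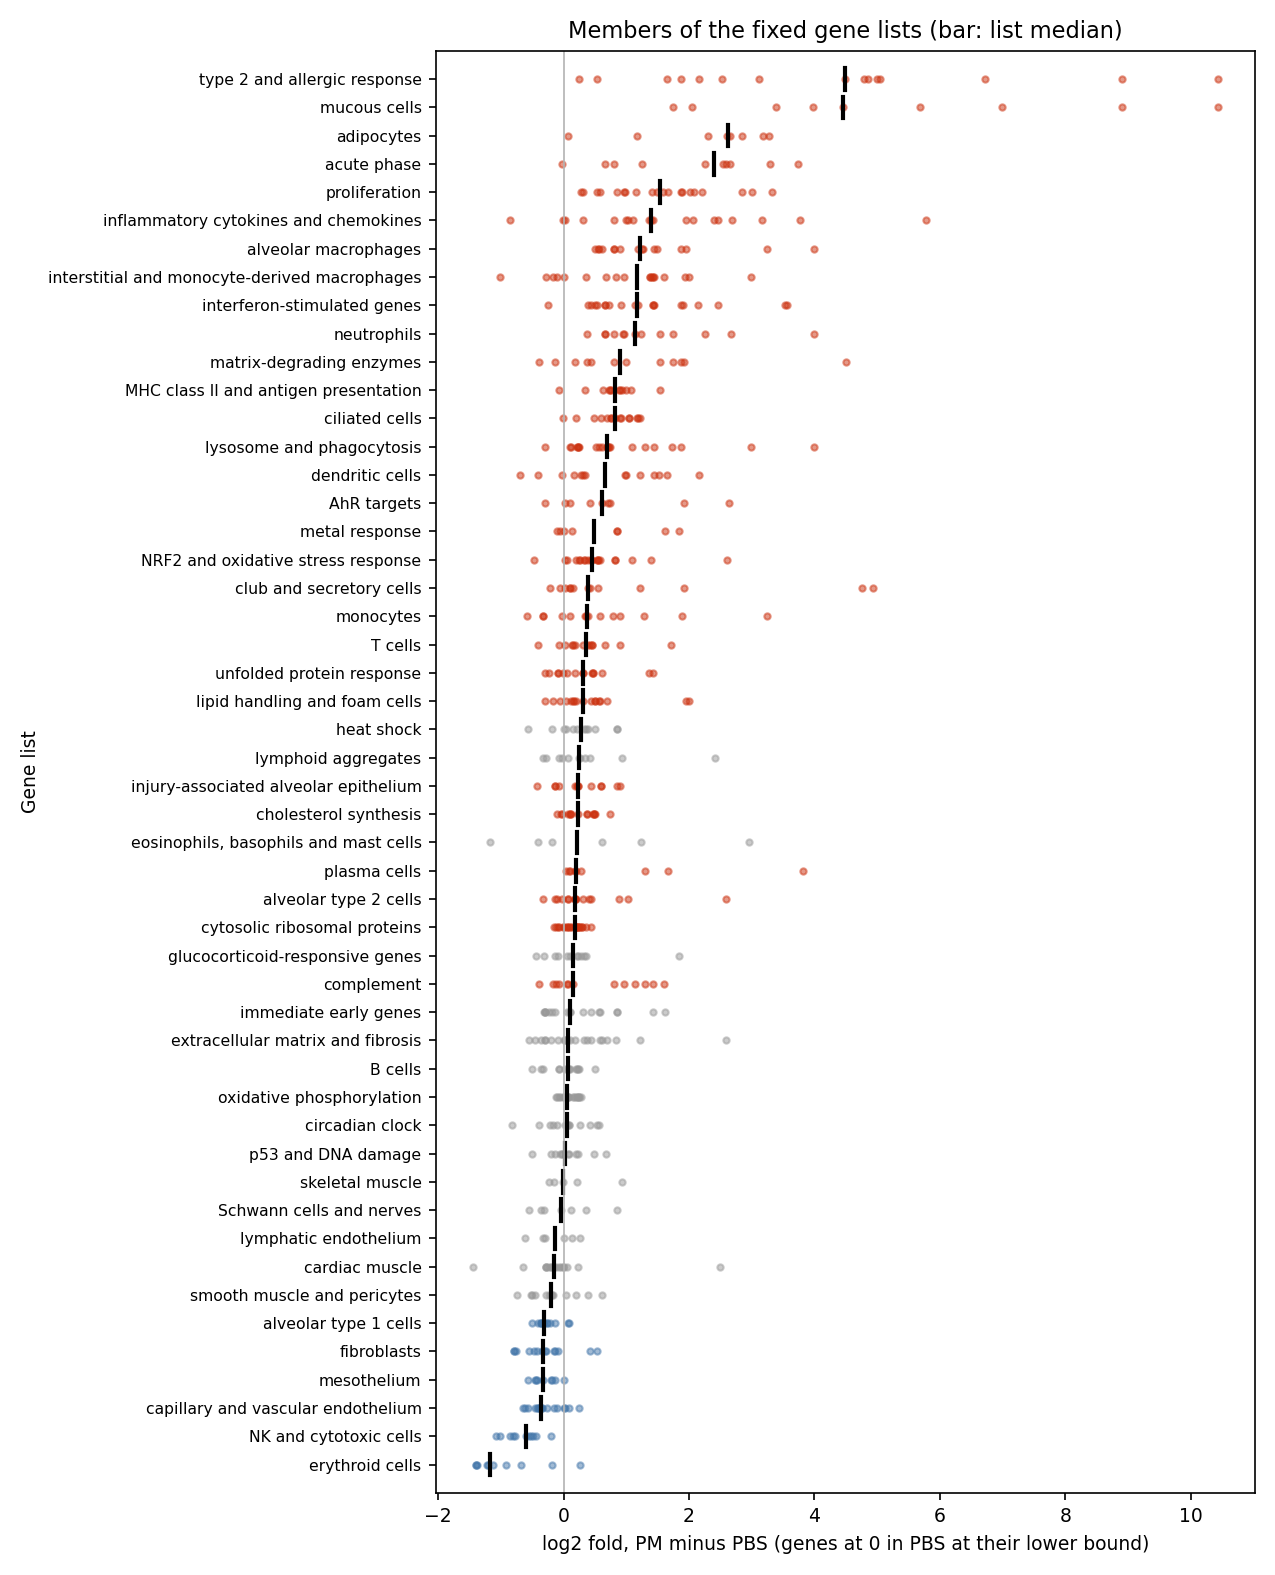
Log2 fold of PM over PBS for each tested member of the 50 gene lists, ordered by list median (black bar), with genes at 0 counts in PBS placed at their lower bound. Red lists stood higher and blue lists lower than other genes by camera with the preset correlation, and grey lists did not pass. Type 2 and mucous cell genes have the highest medians, 4.49 and 4.45, and erythroid genes the lowest, -1.17.

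Of the markers of tissues that a lung piece can carry along, adipocyte genes were higher and erythroid genes lower as lists. Adipocyte genes had a median of 2.63 over 8, with Cidea, a lipid droplet protein, at 3.27 ± 0.64 SE, Thrsp at 1.16 and the hormone Retn at 2.84. Adjusted over the list alone, 5 rose, with 0 over all genes, 5 higher at an unadjusted p below 0.05 and 3 called by DESeq2. Their list medians relative to PBS were 2.26, 0.79 and 2.55 in PM replicates 1, 2 and 3. Erythroid genes had a median of -1.17 over 10, with Hba-a2 at -0.91 and Hbb-b1 at -1.40. In that list 0 fell over all genes, adjusted over the list alone, at an unadjusted p below 0.05 or by DESeq2. Haemoglobin copies are near-identical, so reads may be divided among them. Camera with Benjamini-Hochberg adjustment placed the adipocyte list higher and the erythroid list lower (adjusted p = 1.52e-07 and 0.000147; adjusted p = 0.164 and 0.424 with an estimated correlation). Without PBS replicate 1 the erythroid median was -0.13 (adjusted p = 0.640), without PBS replicate 3 it was -1.77 and without PM replicate 3 it was -0.75. Cardiac muscle genes had a median of -0.15 (0.417), which was 0.77 without PBS replicate 1 (0.00218) and -0.70 without PBS replicate 3 (2.95e-06). Skeletal muscle genes had a median of -0.0014 and a mean of 0.15 with the test pointing up (0.759). Schwann cell genes had a median of -0.03 and a mean of 0.0070 with the test pointing down (0.838).

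Small shifts were seen in biosynthetic lists. Cholesterol synthesis had a median of 0.23 over 15, with Mvd at 0.74 and Fdps at 0.48. The unfolded protein response had a median of 0.31 over 15, with Hyou1 at 0.47, Sdf2l1 at 1.37 and Hspa5 at 0.45, and cytosolic ribosomal proteins 0.18 over 23 with Rplp1 at 0.36, Rpl32 at 0.29 and Rps2 at 0.43. In each, 0 members rose over all genes or adjusted over the list alone, 5, 5 and 4 were higher at an unadjusted p below 0.05, and DESeq2 called 0, 1 and 0. Camera with Benjamini-Hochberg adjustment gave adjusted p = 0.00725, 0.00786 and 0.0293, with adjusted p = 0.400, 0.400 and 0.483 with an estimated correlation. These calls were lost without PBS replicate 3 for cholesterol synthesis (0.172), without PM replicate 2 for the unfolded protein response (0.0587), and without PBS replicate 1 or PM replicate 1 for ribosomal proteins (0.214 and 0.185). Lists that did not pass camera were heat shock (median 0.27, adjusted p = 0.178), extracellular matrix and fibrosis (0.08, 0.182), glucocorticoid-responsive genes (0.16, 0.182), oxidative phosphorylation (0.06, 0.190), immediate early genes (0.10, 0.212), p53 and DNA damage (0.02, 0.838) and the circadian clock (0.06 and a mean of 0.03 with the test pointing down, 0.724). Of these, heat shock passed without PBS replicate 3 (0.00218), extracellular matrix and fibrosis without PM replicate 3 (0.00178), the glucocorticoid list without PM replicate 1 or 2 (0.0340 and 0.0201) and the circadian clock without PBS replicate 1 (median -0.14, 0.0116).

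In all, 35 of 50 lists stood apart from other genes by camera with the preset correlation, 29 higher and 6 lower. The estimated correlations ran from -0.133 for lymphatic endothelium to 0.907 for interferon-stimulated genes. Calls with the preset value rest on that form of the test. A correlation above the preset value is not the whole reason, since lists with estimates below 0.01 also lost their calls. Estimates were -0.0236 for NRF2 targets, -0.00948 for monocytes and 0.00889 for fibroblasts. Each had an adjusted p of 0.164 by camera with an estimated correlation and Benjamini-Hochberg adjustment. With an estimated correlation 0 of 50 passed after Benjamini-Hochberg adjustment and 13 at an unadjusted p below 0.05, and fry of limma, which asks whether a list's members move on balance one way, gave the same numbers, 0 and 13. Changes in either direction within a list passed fry's mixed test for 17 lists.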

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

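The alternatives were chosen before the data were examined, except the use of all 6 files and the removal of Rn45s and haemoglobin genes, chosen after. The 32 called genes became 275 without a filter on low counts, 369 with DESeq2 (259 higher, 110 lower), 206 at an adjusted p of 0.10, 635 with all 6 files as deposited, where the repeat adds a PBS sample with no spread of its own, and 1 to 427 without single libraries. In each of these except the last, all 32 were among the calls. Without PBS replicate 1, PBS replicate 3 or PM replicate 1, the calls held 1, 1 and 9 of the 32, and where 1 PBS library was left it was assumed to vary like the PM libraries. The cause of these moves was not tested. Counts stayed within 1.5 times with median-of-ratios scaling (33), a mean of at least 1 CPM (32), limma-voom (23, of which 22 shared), a 1.5-fold minimum (32), non-robust estimation (23, 15 shared) and without Rn45s and haemoglobin genes (32). The 35 called lists became 0 with an estimated correlation, which replaces a preset of 0.01, and 0 with fry, which asks another question, and 31 to 36 under the other settings. The labels do not say that equal replicate numbers mark a shared batch. With the repeat removed, 2 pairs are left, whose deviations from their group means correlated at -0.0283 and 0.0569. The deviations of 2 PBS libraries mirror each other, so these values can neither show nor exclude a pairing. The replicate block gave 353 genes and 31 lists, 29 of them among the 35. The block fit rests on replicates 1 and 3, since PM replicate 2 has no partner, and leaves little spread between samples from which to judge error. Settings for normalized values (another pseudocount, quantile normalization) were not run, since the files hold counts.

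No called gene changed sign. Log2 folds or list medians that turned sign belonged to genes and lists not called, apart from the club and injury-associated epithelial lists, and the cause was not tested. With the replicate block Nqo1 was at 0.040 and extracellular matrix and fibrosis at -0.098. Without a filter on low counts p53 and DNA damage was at -0.024, eosinophils, basophils and mast cells at -0.19, skeletal muscle at 0.21, Schwann cells and nerves at 0.035. With a mean of at least 1 CPM p53 and DNA damage was at -0.023, eosinophils, basophils and mast cells at -0.18, lymphatic endothelium at 0.0064. With median-of-ratios scaling skeletal muscle was at 0.00018. With all 6 files eosinophils, basophils and mast cells were at -0.15, B cells at -0.0056, Schwann cells and nerves at 0.084. Without Rn45s and haemoglobin genes lymphatic endothelium was at 0.0063. Without single libraries the values ranged from -1.05 to 0.10 for Nqo1, -0.14 to 0.36 for Scgb1a1, -0.0017 to 0.58 for Scgb3a2, -0.21 to 0.25 for Cyp2f2, -0.043 to 0.30 for extracellular matrix and fibrosis, -0.061 to 0.082 for p53 and DNA damage. Further ranges were -0.019 to 0.19 for immediate early genes, -0.25 to 0.36 for glucocorticoid-responsive genes, -0.14 to 0.26 for circadian clock, -0.38 to 0.22 for eosinophils, basophils and mast cells, -0.31 to 0.24 for B cells, -0.021 to 0.33 for lymphoid aggregates. The remaining ones were -0.0039 to 0.41 for injury-associated alveolar epithelium, -0.0017 to 0.44 for club and secretory cells, -0.45 to 0.012 for lymphatic endothelium, -0.70 to 0.77 for cardiac muscle, -0.0084 to 0.15 for skeletal muscle, -0.25 to 0.032 for Schwann cells and nerves. The club, injury-associated epithelial, cholesterol and other list calls lost without 1 library are given in the report. Medians of other called lists that moved by over 1.5 times, and are not given there, were 0.20 for the unfolded protein response, 0.35 for cholesterol synthesis, 0.315 for alveolar type 2 cells, 0.083 for ribosomal proteins and 0.41 for injury-associated epithelium without PBS replicate 1. Without PBS replicate 3 they were 0.27 for complement and 0.13 for cholesterol synthesis. Without PM replicate 1 they were 0.29 for complement, 0.07 for alveolar type 2 cells, 0.35 for injury-associated epithelium, 0.23 for T cells and -0.20 for mesothelium. Without PM replicate 2 they were 0.14 for cholesterol synthesis, 0.19 for the unfolded protein response and 0.20 for T cells, and without PM replicate 3 they were 0.34 for cholesterol synthesis and 0.56 for T cells. Cardiac muscle also passed without PM replicate 2 or 3 (adjusted p = 0.0444 and 0.0466 by camera with Benjamini-Hochberg adjustment). Depth limits genes near the floor, such as Cyp1a1 at 2 to 5 counts. It also leaves the size of a fold uncertain where the PBS libraries together held few counts, such as 2 for Alox15 and 3 for Fgg.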

Other observations

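The tests on the mucous and type 2, ciliated, resident and erythroid genes were chosen after the results were seen, and the count of other splits of the samples before.

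Some genes outside the lists also had large folds with no overlap between groups, though few were called. Cd209e, a C-type lectin chosen after its values were seen, was at 0 counts in both PBS libraries and at 1.99, 1.43 and 2.52 CPM in PM, at least 5.52-fold higher, with an adjusted p of 0.0629 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in 3 of 3 PM libraries. Outside the lists, 82 genes had a fold of at least 4 with all PM libraries above all PBS libraries, and 2 of these were called. Whatever the fold, all PM libraries lay above all PBS libraries for 15.5% of tested genes, where chance gives 10%.

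The mucous and type 2 genes were far higher in PM lung, with a median log2 fold of 4.22 over the 22 genes of the 2 lists. The tables argue against PM replicate 2 as the whole cause: without it the median was 3.08 over the 20 still tested (95% bootstrap interval over members 1.76 to 4.62), and 19 of the 22 had PM replicates 1 and 3 above both PBS libraries. A larger share of conducting airway with an unchanged mix of cells would raise ciliated and club genes about as much as mucous genes. The mucous median of 4.45 exceeded that of the ciliated and club lists together (0.73) by 3.72 (1.48 to 8.06). That argues against airway of an unchanged mix as the whole cause. It cannot decide on a larger share of airway richer in mucous cells, and the comparison was chosen after the results were seen. A response of the lung to PM was not tested apart from these explanations. It may account for the pattern, as may any other difference between the groups that the labels do not record.

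Ciliated genes were higher in PM lung, with a median of 0.81. A larger piece of airway in the PM samples would raise club genes alike, and the club list had a median of 0.39, lower by a difference of 0.417 with a 95% bootstrap interval over members of -0.46 to 0.89. The interval spans 0, so more airway in the PM pieces could account for the rise, and a change of the ciliated cells themselves also stays open.

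Endothelial, fibroblast, alveolar type 1 and mesothelial genes were lower together, with a median of -0.34 over 53 members. Dilution of resident tissue by immune cells would lower all resident types alike. Alveolar type 2 cells, smooth muscle with pericytes, and lymphatic endothelium together had a median of 0.05 over 34 members, higher by 0.394 (0.16 to 0.54). The lists were grouped by their results, however, so this difference decides nothing, and dilution may account for the pattern, as may a response of these cells to PM.

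The fall of erythroid genes in PM lung, a median log2 fold of -1.17, rested on PBS replicate 1, without which it was -0.13 with an adjusted p of 0.640 by camera with Benjamini-Hochberg adjustment.

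Of the 10 splits of the 5 distinct libraries into 2 and 3, 1, the real one, called as many as 32 genes, and the highest of the others called 4. With 10 splits the share cannot fall below 0.05.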
